A study of Rattus norvegicus with 6 samples.

How the data were processed

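Total RNA of whole rat ovaries was hybridized to 6 short-oligonucleotide arrays, 2 for each of 3 groups: ovaries at birth (P0), ovaries at postnatal day 4 (P4), and ovaries taken at birth and cultured for 7 days. Per the labels' protocols, RNA was extracted with Trizol from pools of about 20 ovaries, labelled with biotin and hybridized by the manufacturer's procedures. Groups and replicate numbers were taken from the sample labels. The design text of the series also speaks of a hormone treatment of cultured ovaries, which no sample label gives, so no such groups were formed. Whether either cultured array was treated is therefore unsettled, and the comparisons with culture take both, as labelled, as replicates of 1 condition.

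The table holds linear probe set intensities as deposited, already scaled by the authors to one level per array: the mean left after trimming the lowest and highest 2% was 125.2 on each of the 6 arrays. The algorithm and software behind these intensities are not given in the sources used here. The table has 8799 probe sets and no detection calls. Because the arrays were already scaled, the values were kept without further normalization.

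A pseudocount of 7.7, the 20th percentile of all values in a table with a median of 40, was added before taking log2. The 59 control probe sets were left out of all tests. Of the 8740 others, those with a mean log2 value under the 30th percentile were left out, 2622 in all, and 6118 were tested. Gene symbols came from the array's annotation and were brought up to date by gene number with a RefSeq gene table of the rat: 7018 probe sets had 1 symbol, 308 had several and 1473 had none, 6994 were matched and 9 symbols changed. Among the tested probe sets, 5027 carried 1 symbol, for 3635 genes. Probe set positions are not printed, since no genome sequence was used here.

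One linear model with 3 group means was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend in intensity (3 residual and 6.45 prior degrees of freedom). All 3 comparisons between groups were made, each two-sided, and probe sets with a Benjamini-Hochberg adjusted p under 0.05 over all 6118 were called changed, or passing. With 2 arrays in a group, the smallest two-sided p of an exact permutation test is 0.33, so no such test can pass. No detection calls were used. The highest intensity of 23 control probe sets with no spiked transcript on any single array was 20, a level chosen after the data were seen. In their mean over a group, 98% of the tested probe sets exceeded it in at least 1 group. A change described as at least N-fold has each array of the dimmer group that read under that level set to it, because a log2 change against such a group depends on the pseudocount.

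Gene lists for ovarian cell types, neighbouring tissues, blood, culture stress and pathways, 27 in all, were written before the data were examined, as were the test, the filter, the pseudocount rule and the alternatives, except where stated. Of these lists, 26 were tested with camera at its preset correlation between genes of 0.01, on one probe set per gene (the named one of highest mean). Lists needed at least 4 measured genes, and the 78 list tests were adjusted together. Counts of list members use that probe set. Between P4 and P0, cultured and P0, and cultured and P4, another probe set passed for 4, 9 and 4 list genes whose brightest one did not, and 0, 1 and 1 of these kept that call without each array. For 0, 6 and 6 list genes the brightest probe set passed and another did not. Members were also counted after adjusting their p values over the list alone. Beside each list that passed, the adjusted p from camera with a correlation estimated for the list is given. The remaining list, of reference genes for RNA quality, was described only. The lists name cell types by marker genes, some of which other ovarian cells express too: Krt8 and Krt18 belong to both the granulosa and the surface epithelium lists.

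Genes are named in the text by a rule fixed beforehand. In each comparison these were the 10 largest increases and the 10 largest decreases among called probe sets with 1 symbol whose groups did not overlap, up to 4 members of each list with the smallest p, and Actb and Gapdh. Gapdh is covered here only by control probes. A few further list members outside the rule (Kit, Socs3) were added after their values were seen. The Hbb, Hbb-b1 and Akr1c14 probe sets match families of similar transcripts, so their values can include related genes.

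Per the labels, the chip identifiers fall into 4 batches. P0 and P4 replicates with the same number share a batch (A or B), and each cultured array has its own. The replicate number therefore pairs the P0 and P4 arrays, whose deviations from their group means correlated at 0.33 across probe sets. For P4 against P0, values with the batch as a block (fitted to the P0 and P4 arrays) are given where they change a call, and list medians are given within batches A and B. The cultured arrays cannot be blocked in this way.

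Alternatives were quantile normalization, centring each array on its median, lower and higher pseudocounts (1.925 and 30.8), no filter and a filter at the 60th percentile, no variance trend, the replicate number or the chip batch as a block, only the 4 arrays compared, other thresholds, and leaving out each array in turn. For lists they were fry, an estimated correlation and all named probe sets of a gene. Block fits for the list tests on P0 and P4 arrays alone, and a split of the P0 arrays between the comparisons for the shared change, were added after the data were seen.

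The procedure was tested on simulated data, in 20 draws over 6118 probe sets with the real spread. Between simulated P4 and P0 arrays it called 56.1% of changes of 1 log2 unit, 99% of changes of 2 and 100% of changes of 3, and 6.43% of its calls were false. Between cultured and P4 arrays these figures were 54.9%, 99.3%, 100% and 6.47%. With no simulated change between cultured and P0 arrays it made 0.15 false calls a draw. For P4 against P0, the list test over 3635 genes called 0.385% of lists with no change, and it called a macrophage list shifted by 1 log2 unit in 100% of 50 draws. The simulated genes varied independently, whereas the estimated correlation between genes of a list reached 0.497 (ovarian surface epithelium) in the data. False list calls among correlated genes were therefore not tested.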

Results

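Gene expression was measured in whole rat ovaries on 6 Affymetrix Rat Genome U34 arrays (Set A), a short-oligonucleotide design on which each probe set reports an intensity for 1 transcript or for several similar ones. The arrays fell into 3 groups of 2: ovaries taken on the day of birth (P0), ovaries taken on postnatal day 4 (P4), and ovaries taken at birth and then kept for 7 days in serum-free culture on floating filters (cultured). Each array held RNA pooled from about 20 ovaries, and the labels describe the 2 pools of a group as independent. The cultured arrays are taken here as 2 replicates of 1 condition, as labelled. The series design text mentions a hormone treatment of cultured ovaries, and whether it applied to either of them is not settled by the sources used here. After 59 control probe sets and 2622 dim ones had been left out, 6118 of the 8799 probe sets were tested, covering 3635 named genes. The number of arrays, not a read depth, limits the precision here: the median standard error of a log2 change was 0.259.

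Replicate arrays correlated at 0.962 for P0, 0.969 for P4 and 0.965 for cultured ovaries, across probe sets, which are not independent replicates. P0 and P4 arrays with the same chip ID batch correlated at 0.955 and 0.956, and cultured arrays correlated with the others at 0.913 to 0.935. The array of P0 replicate 1 stood apart on its control probes. Its GAPDH probes, targeting a glycolytic enzyme often used as a reference, read 1386.3 at the 5′ end and 1324.2 at the 3′ end, against 2005.7 to 2673.6 and 2162.3 to 2775.1 on the other arrays. Its BioC spike, a bacterial control transcript, read 296.3 against 148.7 to 225.4 elsewhere. The 3′ to 5′ ratio of the beta-actin probes, a measure of RNA integrity, lay between 1.75 and 2.23 on all 6 arrays, and that of GAPDH between 0.955 and 1.15. The beta-actin gene Actb itself passed in no comparison. Its log2 changes were 0.13 for P4 against P0 (adjusted p = 0.828), -0.29 for cultured against P0 (adjusted p = 0.364) and -0.42 for cultured against P4 (adjusted p = 0.286). The first turned to -0.08 without P0 replicate 2 and the second to 0.13 with quantile normalization.

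The comparison of P4 with P0 ovaries covered the days in which rat germ cells leave their clusters and become enclosed in primordial follicles, the process named in the series title. Genes of the zona pellucida, the glycoprotein coat of the oocyte, were higher at P4: Zp2 read 1620 ± 223 against 310 ± 39.5 at P0 (SD, n = 2; log2 change 2.36, SE 0.18, limma adjusted p = 0.00155). Sycp3 and Sycp1, of the synaptonemal complex that joins homologous chromosomes in meiotic prophase, were lower, with Sycp3 at 42.4 ± 0.919 against 242 ± 81.6 (SD, n = 2; log2 change -2.28, SE 0.27, limma adjusted p = 0.00568). A few granulosa and steroid hormone genes were higher, although neither list passed as a set. Inha, the inhibin alpha subunit, read 1660 ± 439 against 316 ± 111 (SD, n = 2; log2 change 2.38, SE 0.28, limma adjusted p = 0.00568). Cyp19a1, the aromatase that makes estrogens from androgens, was at least 5.33-fold higher at P4 (adjusted p = 0.00995). Altogether 66 of the 6118 probe sets changed, 52 of them higher and 14 lower at P4, for 43 and 9 named genes.

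The oocyte list held 6 measured genes, of which 3 rose, none fell and 3 did not pass, with the same 3 when adjusted over the list alone. Besides Zp2, the coat genes Zp1 and Zp3 rose by 1.65 and 1.67 on the log2 scale (adjusted p = 0.00827 for each). The connexin gene Gja4, which forms junctions between oocyte and granulosa cells, had a log2 change of 0.72 (adjusted p = 0.443), and Kit, the oocyte receptor for kit ligand, one of 0.51 (adjusted p = 0.481). As a set the list shifted upward (camera adjusted p = 5.02e-07), by a median of 1.16 in each chip ID batch, and it had an adjusted p = 0.357 with an estimated correlation. In the meiotic prophase list, 2 of 4 measured genes fell, none rose and 2 did not pass, with 2 lower when adjusted over the list alone. The second of them, Sycp1, fell by 1.80 (adjusted p = 0.0281), while Sycp2 had a log2 change of -0.56 (adjusted p = 0.521). The set shifted downward (camera adjusted p = 0.00182), by medians of -1.46 in batch A and -0.90 in batch B, with an adjusted p = 0.379 with an estimated correlation. Leaving out P4 replicate 1 or P0 replicate 2 ended the call of Zp1 (highest adjusted p = 0.0759), and leaving out any 1 of the 6 arrays ended that of Sycp1 (highest adjusted p = 0.103).

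**Figure D1:**
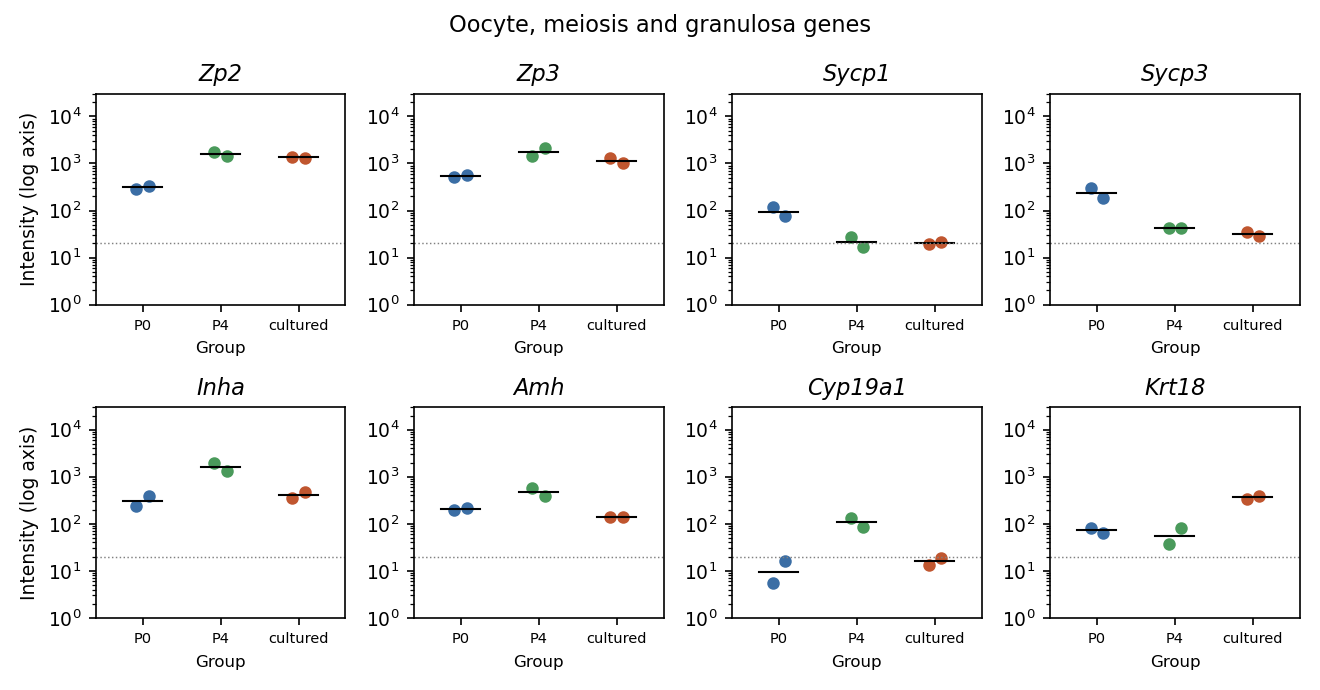
Intensity (log axis) of 8 genes of the oocyte, of meiosis and of granulosa cells, one panel per gene, in P0, P4 and cultured ovaries; points are arrays, black lines geometric means of a group, and the dotted line the highest unspiked control intensity. Zp2 read 310 on average at P0, 1620 at P4 and 1340 in culture, while Sycp3 read 242, 42.4 and 31.4 in the same order.

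Among 20 measured granulosa and pregranulosa genes, 3 rose, none fell and 17 did not pass. The third riser beside Inha and Cyp19a1 was Serpine2, a secreted protease inhibitor (log2 change 1.34, adjusted p = 0.0194). Adjusted over the list alone, 5 were higher and 2 lower, the same counts as with the chip batch as a block. Amh, the anti-Müllerian hormone of growing follicles, had a log2 change of 1.21 (adjusted p = 0.0506, or 0.0102 with the block). The keratin Krt19 had one of -1.28 (adjusted p = 0.0523, or 0.00467 with the block). The list as a set did not pass (camera adjusted p = 0.18) and shifted by medians of 0.14 and 0.07 in batches A and B. Of 19 steroidogenesis genes, 2 rose, none fell and 17 did not pass, with 4 higher when adjusted over the list alone and 4 higher and 1 lower with the block. The risers were Cyp19a1, which belongs to this list too, and Akr1c14. Akr1c14, a 3-alpha-hydroxysteroid dehydrogenase whose probe set also matches related genes and is therefore uncertain, rose by 2.10 (adjusted p = 0.00568). Cyp17a1, the androgen-forming hydroxylase, was at least 3.27-fold higher in its means but did not pass (adjusted p = 0.0523, or 0.00522 with the block). Star, which carries cholesterol into mitochondria, has a pair of probe sets. One was at least 3.42-fold higher (adjusted p = 0.0347) and the brighter one had a log2 change of 2.11 (adjusted p = 0.122, or 0.0018 with the block). The steroidogenesis list missed the threshold without a block (camera adjusted p = 0.0571, median 0.03, mean 0.48, adjusted p = 0.398 with an estimated correlation) and passed with it at the preset correlation (adjusted p = 0.00238), at medians of -0.08 and 0.15 in batches A and B. Cyp19a1 lost its call without P4 replicate 1 (adjusted p = 0.0956). Star lost it without P0 replicate 2, P4 replicate 1 or P4 replicate 2 (highest adjusted p = 0.172), and Serpine2 without any 1 of the 6 (highest adjusted p = 0.0839). The steroidogenesis list passed without P0 replicate 1 (adjusted p = 0.0255) or P4 replicate 2 (adjusted p = 0.00514), and the granulosa and pregranulosa list without P0 replicate 2 (adjusted p = 0.0154). Without P4 replicate 2, Amh, Krt19 and Cyp17a1 passed (adjusted p = 0.0331, 0.0221 and 0.0147), and without P0 replicate 1 the brighter Star probe set did (adjusted p = 0.0324).

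Cell cycle genes shifted upward at P4 (camera adjusted p = 1.09e-09, with medians of 0.71 and 0.54 in batches A and B, and an adjusted p = 0.379 with an estimated correlation). Of 23 measured members, 1 rose, none fell and 22 did not pass, against 14 higher when adjusted over the list alone and 9 higher with the block. Ccnb1, the cyclin that drives entry into mitosis, was the one that rose (log2 change 1.36, adjusted p = 0.0347), and the mitotic kinase Plk1 had a log2 change of 1.06 (adjusted p = 0.0563, or 0.00952 with the block). Cholesterol biosynthesis and uptake genes shifted upward as a set (camera adjusted p = 0.00188, medians 0.32 and 0.34 by batch, adjusted p = 0.547 with an estimated correlation). On the brightest probe set of each, none of the 16 measured passed, against 3 higher adjusted over the list alone and 2 with the block. The sterol reductase Dhcr7 had a log2 change of 1.39 on its brighter probe set (adjusted p = 0.0664, or 0.00249 with the block). Its other one had a log2 change of 1.68 and passed (adjusted p = 0.0301), but not without any single array except P4 replicate 2 (highest adjusted p = 0.151). The decarboxylase Mvd had one of 0.85 (adjusted p = 0.105, or 0.0335 with the block). The smooth muscle and pericyte list also shifted upward (camera adjusted p = 0.0277, medians 0.56 and 0.26 by batch, adjusted p = 0.579 with an estimated correlation). None of its 12 genes passed, against 1 higher adjusted over the list alone and 1 with the block. That gene was the calponin Cnn1 (log2 change 0.96, adjusted p = 0.128, or 0.0308 with the block). The tropomyosin Tpm2 had a log2 change of 0.73 (adjusted p = 0.226). The call of Ccnb1 ended without any single array except P0 replicate 1 (highest adjusted p = 0.179). The smooth muscle and pericyte list lost its call without P0 replicate 1 (adjusted p = 0.339) or P4 replicate 2 (adjusted p = 0.0658). The cholesterol biosynthesis and uptake list lost its call without P0 replicate 2 (adjusted p = 0.0938) or P4 replicate 1 (adjusted p = 0.098), and the brighter Dhcr7 probe set passed without P4 replicate 2 (adjusted p = 0.0307).

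Genes of ribosomal proteins were lower at P4 as a set (camera adjusted p = 5.12e-13, medians -0.33 and -0.37 by batch, adjusted p = 0.357 with an estimated correlation). None of the 40 measured passed, against 12 lower adjusted over the list alone and 2 with the block. Rpl19 had a log2 change of -0.65 (adjusted p = 0.0687, or 0.0308 with the block) and Rps3a one of -0.51 (adjusted p = 0.101). The median of the set, -0.345, became -0.113 with quantile normalization (adjusted p = 0.00237). The macrophage and leukocyte list shifted downward (camera adjusted p = 0.00315, medians -0.49 and -0.51 by batch, adjusted p = 0.555 with an estimated correlation). None of its 18 genes passed, against 2 lower adjusted over the list alone and 4 with the block. C1qb, a complement subunit made by macrophages, was at least 3.59-fold lower in its means but did not pass (adjusted p = 0.0637, or 0.004 with the block). The cathepsin gene Ctss had one of -0.91 (adjusted p = 0.232, or 0.0369 with the block). In the erythroid list, a measure of blood in the tissue, none of 7 genes passed, against 4 lower adjusted over the list alone and 3 with the block. The set shifted downward (camera adjusted p = 0.00208, medians -0.46 and -0.79 by batch, adjusted p = 0.379 with an estimated correlation). The adult beta-globin gene Hbb had a log2 change of -0.66 (adjusted p = 0.291, or 0.0486 with the block), from a probe set that also matches other globins. The embryonic globin Hbe1 was at least 2.04-fold lower in its means but did not pass (adjusted p = 0.162, or 0.0492 with the block). The insulin-like growth factor system shifted downward too (camera adjusted p = 0.0294, medians -0.41 and -0.53 by batch, adjusted p = 0.532 with an estimated correlation). None of its 13 genes passed, against 4 lower both adjusted over the list alone and with the block. The fetal growth factor Igf2 had a log2 change of -1.82 on its brightest probe set (adjusted p = 0.167, or 0.000627 with the block) and -0.51 and -0.47 on its other probe sets. The imprinted noncoding H19 had one of -1.52 (adjusted p = 0.101, or 0.000762 with the block). This last list lost its call at a stricter filter on dim probe sets (adjusted p = 0.131), without P0 replicate 2 (adjusted p = 0.275) and without P4 replicate 1 (adjusted p = 0.187), and its median of -0.31 became -0.614 without P0 replicate 1. C1qb passed without P0 replicate 1 (adjusted p = 0.0324) and H19 without P4 replicate 2 (adjusted p = 0.0358).

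The other lists did not pass as sets between P4 and P0. Stromal collagen and matrix genes had no member past the threshold among 24, with 1 lower adjusted over the list alone and 3 lower with the block (camera adjusted p = 0.366). Postn, the matrix protein periostin, had a log2 change of -1.19 (adjusted p = 0.0525, or 0.00258 with the block). The collagen crosslinker Lox had one of -0.79 (adjusted p = 0.32, or 0.033 with the block). Among 25 extracellular proteases and inhibitors, Serpine2 rose and 24 did not pass, against 1 higher and 2 lower adjusted over the list alone and 1 higher and 3 lower with the block (camera adjusted p = 0.183). The lysosomal protease Ctsl had a log2 change of -0.73 (adjusted p = 0.0561, or 0.0259 with the block). None of 8 ovarian surface epithelium genes passed, against 1 higher and 3 lower adjusted over the list alone and 1 each with the block (camera adjusted p = 0.108). Aldh1a1, a retinoic acid synthesizing enzyme, had a log2 change of 0.82 (adjusted p = 0.105, or 0.0217 with the block). On the brightest probe set of each, none of 36 follicle growth factors and receptors passed, against 2 higher adjusted over the list alone and 2 each way with the block (camera adjusted p = 0.366). Nrg1, neuregulin 1, had a log2 change of 1.21 on its brightest probe set (adjusted p = 0.0948, or 0.00856 with the block) and log2 changes between -0.29 and 1.54 on its 4 others. The highest of these passed (adjusted p = 0.0453), but not without any 1 of the 6 arrays (highest adjusted p = 0.225). The growth factor receptor Fgfr2 had one of -0.96 (adjusted p = 0.162, or 0.0281 with the block). Of 10 adipocyte genes none passed, against 1 higher adjusted over the list alone and 2 with the block (camera adjusted p = 0.46, upward). The median of -0.08, which was 0.01 with quantile normalization, and the mean of 0.24 of the adipocyte list differed in sign. The fatty acid carrier Fabp4 was at least 2.9-fold higher in its means but did not pass (adjusted p = 0.0574, or 0.0021 with the block). Of 10 endothelial genes none passed, against 1 lower with the block, Cav1 (log2 change -1.01, adjusted p = 0.196, or 0.0146 with the block), none adjusted over the list alone and a camera adjusted p = 0.196. The stromal collagen and matrix list passed, downward, without P0 replicate 1 (adjusted p = 0.0246) or P4 replicate 2 (adjusted p = 0.0322), as did the extracellular proteases and inhibitors (adjusted p = 0.0241 and 0.00838). Without P4 replicate 2 the endothelial and ovarian surface epithelium lists also passed downward (adjusted p = 0.0198 and 0.00497), and Fabp4 passed upward (adjusted p = 0.00607).

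None of 24 immediate early and stress genes passed, against 1 higher both adjusted over the list alone and with the block (camera adjusted p = 0.0814). This was the heat shock gene Hsph1 (log2 change 0.97, adjusted p = 0.0681, or 0.0128 with the block), whose other probe set read 0.22. None of 24 acute phase and inflammation genes passed, against 1 lower adjusted over the list alone and 1 each way with the block (camera adjusted p = 0.512). The protease inhibitor A2m had a log2 change of -1.84 on its brightest probe set (adjusted p = 0.0583, or 0.00739 with the block) and log2 changes between -0.42 and 0.39 on its 3 others. Of 13 steroid receptors and chaperones none passed, against 1 higher both adjusted over the list alone and with the block (camera adjusted p = 0.82). It was the chaperone Fkbp4, at 0.79 (adjusted p = 0.107, or 0.0305 with the block). For steroid receptors and chaperones the median of -0.02, which was 0.05 with quantile normalization and 0.06 with median centring, and the mean of 0.01 differed in sign. Of 53 oxidative phosphorylation genes none passed, also when adjusted over the list alone, against 1 higher with the block (camera adjusted p = 0.24). It was the complex I subunit Ndufb1 (log2 change 0.94, adjusted p = 0.0893, or 0.0246 with the block). No member passed, even adjusted over the list alone, among 21 hypoxia and glycolysis genes (camera adjusted p = 0.366), 14 apoptosis genes (camera adjusted p = 0.366) and 12 nerve genes (camera adjusted p = 0.371). The same held for 9 skeletal muscle genes (camera adjusted p = 0.369) and 9 genes of kidney, adrenal, oviduct and liver (camera adjusted p = 0.539). Their log2 changes of lowest p included -0.52 for the angiogenic factor Vegfa, 0.54 for the executioner protease Casp6 (1.43 on its dimmer probe set, adjusted p = 0.362), -0.73 for the neuronal filament gene Prph, and -0.29 for the embryonic myosin Myh3. The immediate early and stress list passed upward without P0 replicate 2 (adjusted p = 0.00774) or P4 replicate 1 (adjusted p = 0.000772), and the hypoxia and glycolysis list downward without P0 replicate 1 (adjusted p = 0.0172). A2m passed without P4 replicate 2 (adjusted p = 0.00607).

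Outside the lists, the largest increases at P4 included Alox15, a lipoxygenase (at least 4.3-fold, adjusted p = 0.00568), and the phospholipase Pld1 (log2 change 2.44, SE 0.26, adjusted p = 0.00568). They also included the maintenance DNA methyltransferase Dnmt1 (log2 change 2.18, SE 0.33, adjusted p = 0.0222). The other probe set of Alox15 had a log2 change of 0.18, and those of Pld1 and Dnmt1 had 1.24 and 0.99. The membrane protein gene Pllp was at least 4.05-fold higher (adjusted p = 0.00568) and Abat, which degrades the transmitter GABA, at least 3.62-fold (adjusted p = 0.0146). So was the digestive carboxypeptidase Cpa1 at least 5.88-fold (adjusted p = 0.0301). Of the 9 named genes that fell, Sycp3 and Sycp1 belonged to a list. The others included the cadherin Cdh22 (log2 change -1.92, adjusted p = 0.0262), the tetraspanin Tspan8 (-1.85, adjusted p = 0.00568) and the endothelial gene Egfl7 (-1.75, adjusted p = 0.0401). They also included the fructose transporter Slc2a5 (-1.45, adjusted p = 0.0185, or -0.75 on its other probe set), the carboxylesterase Ces1dl1 (-1.43, adjusted p = 0.0301). The last were the prostaglandin D synthase Hpgds (at least 1.72-fold lower, adjusted p = 0.0453) and the chemokine Cxcl13 (-1.40, adjusted p = 0.0376). With the batch as a block on the P0 and P4 arrays, 314 probe sets passed (194 higher and 120 lower), among them all 66. That fit had fewer residual degrees of freedom than the main one and was not tested by simulation. Of the 24 named genes past the threshold, 9 also passed without each array in turn: Alox15, Pld1, Inha, Zp2, Zp3, Pllp, Sycp3, Tspan8 and Akr1c14. The others lost the call without at least 1 array, with adjusted p up to 0.245 for Egfl7. The count of 66 itself fell to 15 without P4 replicate 1, to 16 without P0 replicate 2 and to 23 without either cultured array.

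The comparison of cultured with P0 ovaries set ovaries that spent 7 days in culture against the stage from which they were taken. Zona pellucida genes were higher after culture, with Zp2 at 1340 ± 45.3 against 310 ± 39.5 (SD, n = 2; log2 change 2.09, SE 0.18, limma adjusted p = 0.000239). Sycp3 was lower at 31.4 ± 4.6 against 242 ± 81.6 (SD, n = 2; log2 change -2.64, SE 0.27, limma adjusted p = 0.000587). The beta-globin probe set Hbb, a marker of red blood cells, fell from 3770 ± 50.7 to 33.9 ± 14.3 (SD, n = 2; log2 change -6.55, SE 0.26, limma adjusted p = 1.39e-06). Among genes that rose were 7 of 18 of the macrophage list, 10 of 24 of the inflammation list and 8 of 25 of the protease list, and these list shifts did not pass with an estimated correlation (adjusted p = 0.494, 0.379 and 0.494). Spp1, the secreted phosphoprotein osteopontin, read 1190 ± 409 against 31 ± 5.3 (SD, n = 2; log2 change 4.92, SE 0.28, limma adjusted p = 1.39e-05). The complement component C3 was at least 19.3-fold higher (adjusted p = 0.000138). Of 6118 probe sets, 332 changed, 213 higher and 119 lower, for 160 and 74 named genes. With each array centred on its median, 272 changed, 205 higher and 67 lower, which raised the share of higher calls from 64.2% to 75.4%. Leaving out cultured replicate 2 lowered the count of 332 to 90, cultured replicate 1 to 112, P0 replicate 2 to 149 and P0 replicate 1 to 178.

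Of the 6 oocyte genes, 3 rose, none fell and 3 did not pass, with 4 higher adjusted over the list alone (camera adjusted p = 0.00126, median 1.09, adjusted p = 0.379 with an estimated correlation). Zp1 and Zp3 rose by 1.15 (adjusted p = 0.0145) and 1.08 (adjusted p = 0.0216). In the meiotic prophase list 2 of 4 genes fell, with 3 lower adjusted over the list alone (camera adjusted p = 0.00188, median -1.36, adjusted p = 0.379 with an estimated correlation), Sycp1 by 1.85 (adjusted p = 0.00817). Of 20 granulosa and pregranulosa genes, 2 rose, 1 fell and 17 did not pass, against 3 higher and 5 lower adjusted over the list alone, and the set did not pass (camera adjusted p = 0.481). The epithelial keratins Krt18 and Krt8 rose by 2.21 (adjusted p = 0.00469) and 0.92 (adjusted p = 0.0323), and follistatin, Fst, which binds activin, fell by 1.64 (adjusted p = 0.00407). The same keratins were the 2 risers among 8 ovarian surface epithelium genes, where none fell and 6 did not pass, with 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.24). On the brightest probe set of each, none of 19 steroidogenesis genes passed, also when adjusted over the list alone (camera adjusted p = 0.262). Star had a log2 change of 1.74 on its brighter probe set (adjusted p = 0.109), while its dimmer one was higher after culture and passed (adjusted p = 0.0102). Nr5a1, a transcription factor of steroid-making cells, had a log2 change of -1.10 (adjusted p = 0.0622). Zp1, Zp3 and Krt8 each lost the call without any 1 of the P0 and cultured arrays (highest adjusted p = 0.104, 0.167 and 0.161). Krt18 and Fst lost it without cultured replicate 2 (adjusted p = 0.0679 and 0.0636), and Sycp1 without P0 replicate 1 or either cultured array (highest adjusted p = 0.0597). The brighter Star probe set passed without P0 replicate 1 (adjusted p = 0.022), and the dimmer one lost its call without P0 replicate 2 or cultured replicate 2 (highest adjusted p = 0.0762).

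Among 18 macrophage and leukocyte genes, 7 rose, none fell and 11 did not pass, with 8 higher and 1 lower adjusted over the list alone. Lyz2, the lysozyme of macrophages, rose from 126 ± 21.6 to 1610 ± 927 (SD, n = 2; log2 change 3.48, limma adjusted p = 0.000587). The Fc receptor Fcgr2b was at least 5.28-fold higher (adjusted p = 0.00469), and the leukocyte membrane protein Cd53 and the macrophage gene Aif1 rose by 2.22 (adjusted p = 0.012) and 2.24 (adjusted p = 0.0136). The set shifted upward (camera adjusted p = 2.73e-05, median 0.75, adjusted p = 0.494 with an estimated correlation). In the erythroid list 3 of 7 genes fell and 4 did not pass, with 4 lower adjusted over the list alone (camera adjusted p = 2.45e-06, median -0.87, adjusted p = 0.357 with an estimated correlation). Hbb-b1, a globin probe set that shares sequence with Hbb and is uncertain for that reason, fell by 5.88 (adjusted p = 1.71e-06) and Hbe1 was at least 2.04-fold lower (adjusted p = 0.0414). Among 24 acute phase and inflammation genes, 10 rose, 1 fell and 13 did not pass, with 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.98e-10, median 0.79, adjusted p = 0.379 with an estimated correlation). Beside Spp1 and C3, the iron-sequestering lipocalin Lcn2 rose by 3.38 (adjusted p = 6e-05) and the complement protease C1s by 2.53 (adjusted p = 0.000159). Socs3, an inhibitor of cytokine signalling, was lower (adjusted p = 0.0113). Among 25 extracellular proteases and inhibitors, 8 rose, none fell and 17 did not pass, with 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.73e-06, median 0.51, adjusted p = 0.494 with an estimated correlation). The metalloprotease gene Mmp7 rose by 4.02 (adjusted p = 2.09e-05), Mmp9 was at least 3.05-fold higher (adjusted p = 0.00364) and Mmp12, the elastase of macrophages, at least 10.4-fold (adjusted p = 0.000152). The call of Cd53 ended without P0 replicate 2 or cultured replicate 1 (highest adjusted p = 0.0685). That of Aif1 ended without either P0 array or cultured replicate 1 (highest adjusted p = 0.0756), and that of Hbe1 without any P0 or cultured array (highest adjusted p = 0.182). Socs3 lost its call without P0 replicate 2 or cultured replicate 2 (highest adjusted p = 0.085).

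**Figure D2:**
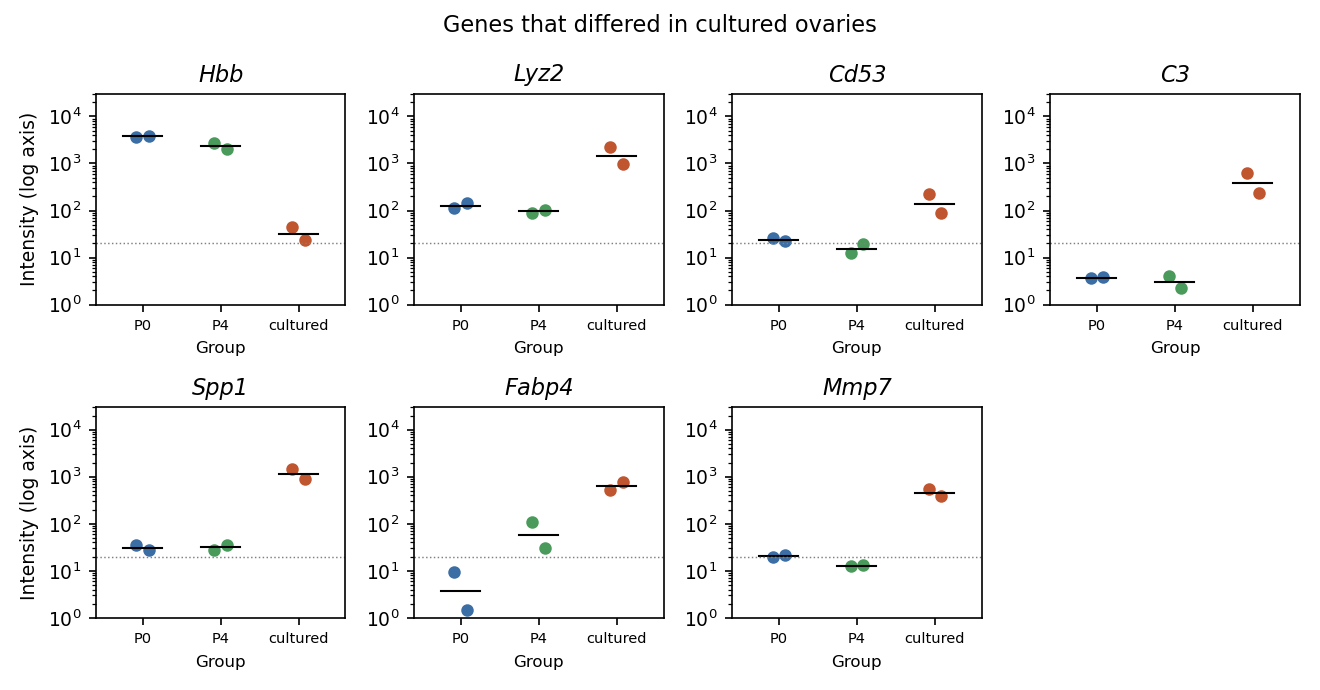
Intensity (log axis) of 7 genes that differed between cultured and other ovaries, one panel per gene, in P0, P4 and cultured ovaries; points are arrays, black lines geometric means of a group, and the dotted line the highest unspiked control intensity. Hbb read 3770 on average at P0, 2410 at P4 and 33.9 in culture, while Spp1 read 31, 31.8 and 1190 in the same order.

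Of 10 adipocyte genes, 5 rose, none fell and 5 did not pass, with the same number adjusted over the list alone (camera adjusted p = 2.63e-05, median 1.18, adjusted p = 0.398 with an estimated correlation). Fabp4 was at least 31.7-fold higher after culture (adjusted p = 0.000248). The lipoprotein lipase gene Lpl rose by 2.95 (adjusted p = 0.000283) and the desaturase Scd by 4.48 (adjusted p = 0.00219). The complement factor Cfd was at least 11.1-fold higher (adjusted p = 0.000826). Cholesterol biosynthesis and uptake genes shifted upward (camera adjusted p = 1.49e-05, median 0.70, adjusted p = 0.453 with an estimated correlation). Of its members, 2 of 16 were higher, none lower and 14 did not pass, against 9 higher adjusted over the list alone. These were the squalene epoxidase Sqle (log2 change 0.99, adjusted p = 0.0237) and the isomerase Idi1 (adjusted p = 0.029). Hypoxia and glycolysis genes shifted upward (camera adjusted p = 0.00861, median 0.38, adjusted p = 0.494 with an estimated correlation), with none of 21 passing and 2 higher adjusted over the list alone. The aldolase Aldoc had a log2 change of 1.33 (adjusted p = 0.0527) and the lactate transporter Slc16a3 one of 1.00 (adjusted p = 0.0653). Of 24 immediate early and stress genes, 3 rose, none fell and 21 did not pass, with 4 higher adjusted over the list alone (camera adjusted p = 0.0221, median 0.27, adjusted p = 0.547 with an estimated correlation). They were the mitochondrial superoxide dismutase Sod2 (log2 change 1.33, adjusted p = 0.0237), the quinone reductase Nqo1 (1.22, adjusted p = 0.0237) and Hsph1 (1.12, adjusted p = 0.0157), whose other probe set had a log2 change of 0.04. Sqle lost its call without P0 replicate 2 or either cultured array (highest adjusted p = 0.14), and Idi1, Sod2, Nqo1 and Hsph1 without any P0 or cultured array (highest adjusted p = 0.18, 0.153, 0.145 and 0.135). The hypoxia and glycolysis list and the immediate early and stress list each lost the call without P0 replicate 1 (adjusted p = 0.23 and 0.277) or cultured replicate 2 (adjusted p = 0.0555 and 0.061). The former also lost it with the stricter filter (adjusted p = 0.0502), and the median of the latter, 0.27, became 0.412 without cultured replicate 1. Aldoc passed without P0 replicate 2 (adjusted p = 0.0435), P4 replicate 1 (0.0288) or P4 replicate 2 (0.0293).

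Stromal collagen and matrix genes shifted downward after culture (camera adjusted p = 0.00686, median -0.34, adjusted p = 0.585 with an estimated correlation). Of 24 measured, 2 were lower, none was higher and 22 did not pass, against 1 higher and 5 lower adjusted over the list alone. Periostin, Postn, fell by 1.55 (adjusted p = 0.0066) and elastin, Eln, by 1.91 (adjusted p = 0.0319). Genes of ribosomal proteins shifted downward (camera adjusted p = 1.79e-11, median -0.371, adjusted p = 0.357 with an estimated correlation). Of 40 measured, 4 were lower, none was higher and 36 did not pass, against 17 lower adjusted over the list alone. With quantile normalization their median was -0.00907 (adjusted p = 0.315) and none passed, including Rps29 and Rpl27a. In the values as deposited these fell by 0.68 (adjusted p = 0.00914) and 0.70 (adjusted p = 0.0109), against 0.07 and 0.20 with quantile normalization. Cell cycle genes shifted upward as a set (camera adjusted p = 0.0277, median 0.31, adjusted p = 0.585 with an estimated correlation), with none of 23 passing, also when adjusted over the list alone. Aurkb, a mitotic kinase, had a log2 change of 1.16 (adjusted p = 0.0621) and Plk1 one of 0.79 (adjusted p = 0.0747). Follicle growth factors and receptors shifted downward (camera adjusted p = 0.0333, median -0.32, adjusted p = 0.494 with an estimated correlation), with none of 36 passing, also when adjusted over the list alone. Fgfr2 had a log2 change of -1.08 on its brightest probe set (adjusted p = 0.0584) and between -1.30 and -0.30 on its 3 others. The lowest of these passed (adjusted p = 0.029), but not without P0 replicate 2 or either cultured array (highest adjusted p = 0.168). Tgfb3, a transforming growth factor, had a log2 change of -0.85 (adjusted p = 0.0621). Eln lost its call without P0 replicate 2 or cultured replicate 2 (highest adjusted p = 0.218), Postn without cultured replicate 2 (adjusted p = 0.0597), and Rps29 and Rpl27a without either cultured array (highest adjusted p = 0.0936 and 0.109). The stromal collagen and matrix list lost it without P0 replicate 2 (adjusted p = 0.198) or cultured replicate 2 (adjusted p = 0.0911). The cell cycle and the follicle growth factors and receptors lists lost it without P0 replicate 2 (adjusted p = 0.303 and 0.144) or cultured replicate 1 (adjusted p = 0.143 and 0.0821). They also lost it at the stricter filter (adjusted p = 0.137 and 0.177), with the chip batch as a random block (adjusted p = 0.0918 and 0.0859) and with all probe sets of a gene (adjusted p = 0.0823 and 0.131). Without P0 replicate 1 the median of the cell cycle list, 0.31, became 0.484. Aurkb and Fgfr2 passed without P4 replicate 1 (adjusted p = 0.0385 and 0.0456) or P4 replicate 2 (adjusted p = 0.0344 and 0.0459).

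The remaining lists did not pass between cultured and P0 ovaries. The insulin-like growth factor system had 1 of 13 genes lower, none higher and 12 not passing, also when adjusted over the list alone (camera adjusted p = 0.0725). That gene was Igfbp2, a binding protein of insulin-like growth factors, which fell by 1.01 (adjusted p = 0.045). Of 10 endothelial genes 1 rose and 9 did not pass, against 1 each way adjusted over the list alone (camera adjusted p = 0.24). The adhesion molecule Icam1 rose (log2 change 1.19, adjusted p = 0.0431, or 0.56 on its other probe set) and Cav1 had a log2 change of -1.29 (adjusted p = 0.0515). One of 13 steroid receptors and chaperones fell and 12 did not pass, also when adjusted over the list alone (camera adjusted p = 0.55). The median of 0.04 and mean of -0.11 differed in sign. The gene that fell was the heat shock protein Hsp90ab1 (log2 change -0.59, adjusted p = 0.0394, or 0.445 with quantile normalization). Of 53 oxidative phosphorylation genes 1 fell and 52 did not pass, also when adjusted over the list alone (camera adjusted p = 0.583). It was the cytochrome oxidase subunit Cox6c, at -2.13 on one probe set (adjusted p = 0.000797) and -0.38 on the other. None of 12 smooth muscle and pericyte genes (camera adjusted p = 0.318) or of 9 genes of kidney, adrenal, oviduct and liver (camera adjusted p = 0.358) passed, also when adjusted over the list alone. The smooth muscle myosin Myh11 had a log2 change of 1.19 on its brighter probe set (adjusted p = 0.083) and -0.16 on the other, and the fetal plasma protein Afp was at least 1.95-fold lower in its means (adjusted p = 0.084). None of 9 skeletal muscle genes passed, against 2 lower adjusted over the list alone (camera adjusted p = 0.183). These were Myh3 at -0.83 (adjusted p = 0.0508) and the troponin Tnni1, at least 1.33-fold lower in its means (adjusted p = 0.0958). In the nerve list 2 of 12 genes rose, none fell and 10 did not pass, also when adjusted over the list alone (camera adjusted p = 0.71, median -0.33, mean 0.07, differing in sign). They were the glial calcium-binding protein S100b (at least 7.72-fold, adjusted p = 0.000538) and neuropeptide Y, Npy (log2 change 1.41, adjusted p = 0.0157). None of 14 apoptosis genes passed, also when adjusted over the list alone (camera adjusted p = 0.71, median -0.13, mean 0.03, differing in sign), with Casp6 at 0.73 (adjusted p = 0.0811, or 0.36 on its dimmer probe set) and the death agonist Bid at 0.77 (adjusted p = 0.163). Npy lost the call without any P0 or cultured array (highest adjusted p = 0.116). Igfbp2 and Icam1 lost the call without any P0 or cultured array (highest adjusted p = 0.25 and 0.221), and Hsp90ab1 without P0 replicate 1 or either cultured array (highest adjusted p = 0.193). The insulin-like growth factor system list passed without P0 replicate 1 (adjusted p = 0.0207), P4 replicate 1 (0.0462), P4 replicate 2 (0.0397) or cultured replicate 2 (0.0188). The smooth muscle and pericyte list passed, upward, without cultured replicate 2 (adjusted p = 0.00617), as did the brighter Myh11 probe set (adjusted p = 0.0437), while Afp passed downward (adjusted p = 0.0427). Cav1 passed without P0 replicate 1 (adjusted p = 0.0428), P4 replicate 1 (0.0402) or P4 replicate 2 (0.0405).

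The comparison of cultured with P4 ovaries set the culture period against a later stage reached in the animal, so that age and culture differed together. Inha, Amh and Cyp19a1, of the granulosa list, were lower in culture. Inha read 412 ± 71.8 against 1660 ± 439 (SD, n = 2; log2 change -1.98, SE 0.28, limma adjusted p = 0.00465). Amh read 138 ± 1.06 against 488 ± 139 (SD, n = 2; log2 change -1.74, SE 0.24, limma adjusted p = 0.00407). Cyp19a1 was at least 5.33-fold lower in culture (adjusted p = 0.008). The macrophage gene Lyz2 was higher, at 1610 ± 927 against 95.9 ± 9.76 (SD, n = 2; log2 change 3.84, SE 0.35, limma adjusted p = 0.000366). Zona pellucida and synaptonemal complex genes did not pass, with log2 changes of -0.27 for Zp2 (adjusted p = 0.602) and -0.36 for Sycp3 (adjusted p = 0.643). Of 6118 probe sets, 170 changed, 132 higher and 38 lower in culture, for 95 and 28 named genes. The count of 170 fell to 86 without cultured replicate 1, to 95 without cultured replicate 2 and to 101 without P4 replicate 1.

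Of 20 granulosa and pregranulosa genes, 2 rose, 3 fell and 15 did not pass, with 2 higher and 8 lower adjusted over the list alone. Those that fell were Inha, Amh and Cyp19a1, and those that rose were the keratins Krt18 (log2 change 2.57, adjusted p = 0.00214) and Krt8 (log2 change 1.48, adjusted p = 0.00456). The set shifted downward (camera adjusted p = 0.0044, median -0.585, adjusted p = 0.379 with an estimated correlation). Of 19 steroidogenesis genes, 2 rose, 2 fell and 15 did not pass, with 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.287). Cyp19a1, in this list too, and Akr1c14 fell, the latter by 1.52 (adjusted p = 0.00465), while Hsd17b2, which inactivates estradiol and testosterone, was at least 2.12-fold higher (adjusted p = 0.0232) and the mitochondrial cholesterol-binding protein gene Tspo rose by 1.11 (adjusted p = 0.0258). The ovarian surface epithelium list shifted upward (camera adjusted p = 0.00688, median 0.31, adjusted p = 0.555 with an estimated correlation). The same keratins were its 2 risers among 8 genes, none fell and 6 did not pass, also when adjusted over the list alone. None of 6 oocyte genes (camera adjusted p = 0.076) or 4 meiotic prophase genes (camera adjusted p = 0.371) passed, also when adjusted over the list alone. The call of Inha ended without cultured replicate 1 (adjusted p = 0.0864), that of Amh without either cultured array (highest adjusted p = 0.0542) and that of Cyp19a1 without P4 replicate 1 or either cultured array (highest adjusted p = 0.0908). Hsd17b2 lost the call without either P4 array or cultured replicate 1 (highest adjusted p = 0.152), and Tspo without any P4 or cultured array (highest adjusted p = 0.177). The granulosa and pregranulosa list lost its call with the stricter filter (adjusted p = 0.145). The ovarian surface epithelium list lost it without P4 replicate 1 (adjusted p = 0.144, median -0.0423), and the steroidogenesis list passed, downward, without P4 replicate 2 (adjusted p = 0.0466). The median of the ovarian surface epithelium list became 0.658 without P4 replicate 2 and 0.197 without cultured replicate 1.

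Among 18 macrophage and leukocyte genes, 8 rose, none fell and 10 did not pass, with 11 higher adjusted over the list alone (camera adjusted p = 1.64e-11, median 1.14, adjusted p = 0.379 with an estimated correlation). C1qb was at least 14-fold higher (adjusted p = 0.00103), Aif1 was at least 8.36-fold higher (adjusted p = 0.0046) and Ctss rose by 2.56 (adjusted p = 0.00212). Among 24 acute phase and inflammation genes, 11 rose, 1 fell and 12 did not pass, with 15 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.18e-13, median 0.87, adjusted p = 0.357 with an estimated correlation). Spp1 rose by 4.89 (adjusted p = 1.25e-05), C3 was at least 19.3-fold higher (adjusted p = 0.000121) and Lcn2 rose by 3.21 (adjusted p = 8.93e-05). Of 25 extracellular proteases and inhibitors, 8 rose, none fell and 17 did not pass, with 14 higher and 2 lower adjusted over the list alone (camera adjusted p = 2.76e-09, median 0.64, adjusted p = 0.398 with an estimated correlation). Mmp7 was at least 22.8-fold and Mmp12 at least 10.4-fold higher (adjusted p = 9.94e-06 and 0.000114). A2m belongs to both of these lists and rose by 2.73 on its brightest probe set (adjusted p = 0.00465), with log2 changes between -0.17 and 0.54 on its 3 others. In the adipocyte list 5 of 10 genes rose and 5 did not pass, also when adjusted over the list alone (camera adjusted p = 1.32e-06, median 1.16, adjusted p = 0.379 with an estimated correlation). Among them were Lpl (log2 change 2.12, adjusted p = 0.00251) and Fabp4 (log2 change 3.26, adjusted p = 0.00706). In the erythroid list 2 of 7 genes fell and 5 did not pass, also when adjusted over the list alone (camera adjusted p = 0.000891, median -0.30, adjusted p = 0.379 with an estimated correlation). Hbb fell by 5.89 (adjusted p = 3.75e-06), and its related probe set Hbb-b1 also fell (adjusted p = 4.91e-06). Fabp4 lost its call without cultured replicate 1 or cultured replicate 2 (highest adjusted p = 0.118) and A2m without cultured replicate 1 (adjusted p = 0.0855). The adipocyte median became 1.77 without cultured replicate 1, and the erythroid median -0.504 without P4 replicate 2.

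Hypoxia and glycolysis genes shifted upward in culture against P4 (camera adjusted p = 0.000226, median 0.43, adjusted p = 0.398 with an estimated correlation). Of 21 measured, 2 were higher, none was lower and 19 did not pass, against 7 higher and 1 lower adjusted over the list alone. Aldoc rose by 1.93 (adjusted p = 0.0146) and Slc16a3 by 1.40 (adjusted p = 0.0222). Cell cycle genes shifted downward (camera adjusted p = 0.000775, median -0.36, adjusted p = 0.494 with an estimated correlation), with none of 23 passing, also when adjusted over the list alone. The kinase gene Cdk4 had a log2 change of -0.74 (adjusted p = 0.0795) and Cdk1 one of -0.68 (adjusted p = 0.227). Stromal collagen and matrix genes shifted downward (camera adjusted p = 0.0299, median -0.31, adjusted p = 0.608 with an estimated correlation). Of 24 measured, 1 was lower, none was higher and 23 did not pass, against 2 each way adjusted over the list alone. The elastic fibre gene Fbln5 fell by 1.45 (adjusted p = 0.00894). The cholesterol biosynthesis and uptake list shifted upward (camera adjusted p = 0.0444, median 0.20, adjusted p = 0.608 with an estimated correlation). None of 16 passed, also when adjusted over the list alone, with Idi1 at 1.25 (adjusted p = 0.0879). Aldoc, Slc16a3 and Fbln5 lost the call without P4 replicate 1 or either cultured array (highest adjusted p = 0.149, 0.164 and 0.094). The cell cycle list lost it without P4 replicate 1 (adjusted p = 0.0946) and the stromal collagen and matrix list without P4 replicate 2 (adjusted p = 0.329) or cultured replicate 2 (0.371). The stromal collagen and matrix list and the cholesterol biosynthesis and uptake list lost it with quantile normalization (adjusted p = 0.0687 and 0.0521) or the stricter filter (adjusted p = 0.0523 for each). The cholesterol biosynthesis and uptake list also lost it without P4 replicate 2 (adjusted p = 0.37), cultured replicate 1 (0.122) or cultured replicate 2 (0.0845), and with the chip batch as a random block (0.127). Idi1 passed without P4 replicate 1 (adjusted p = 0.0246).

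**Figure D3:**
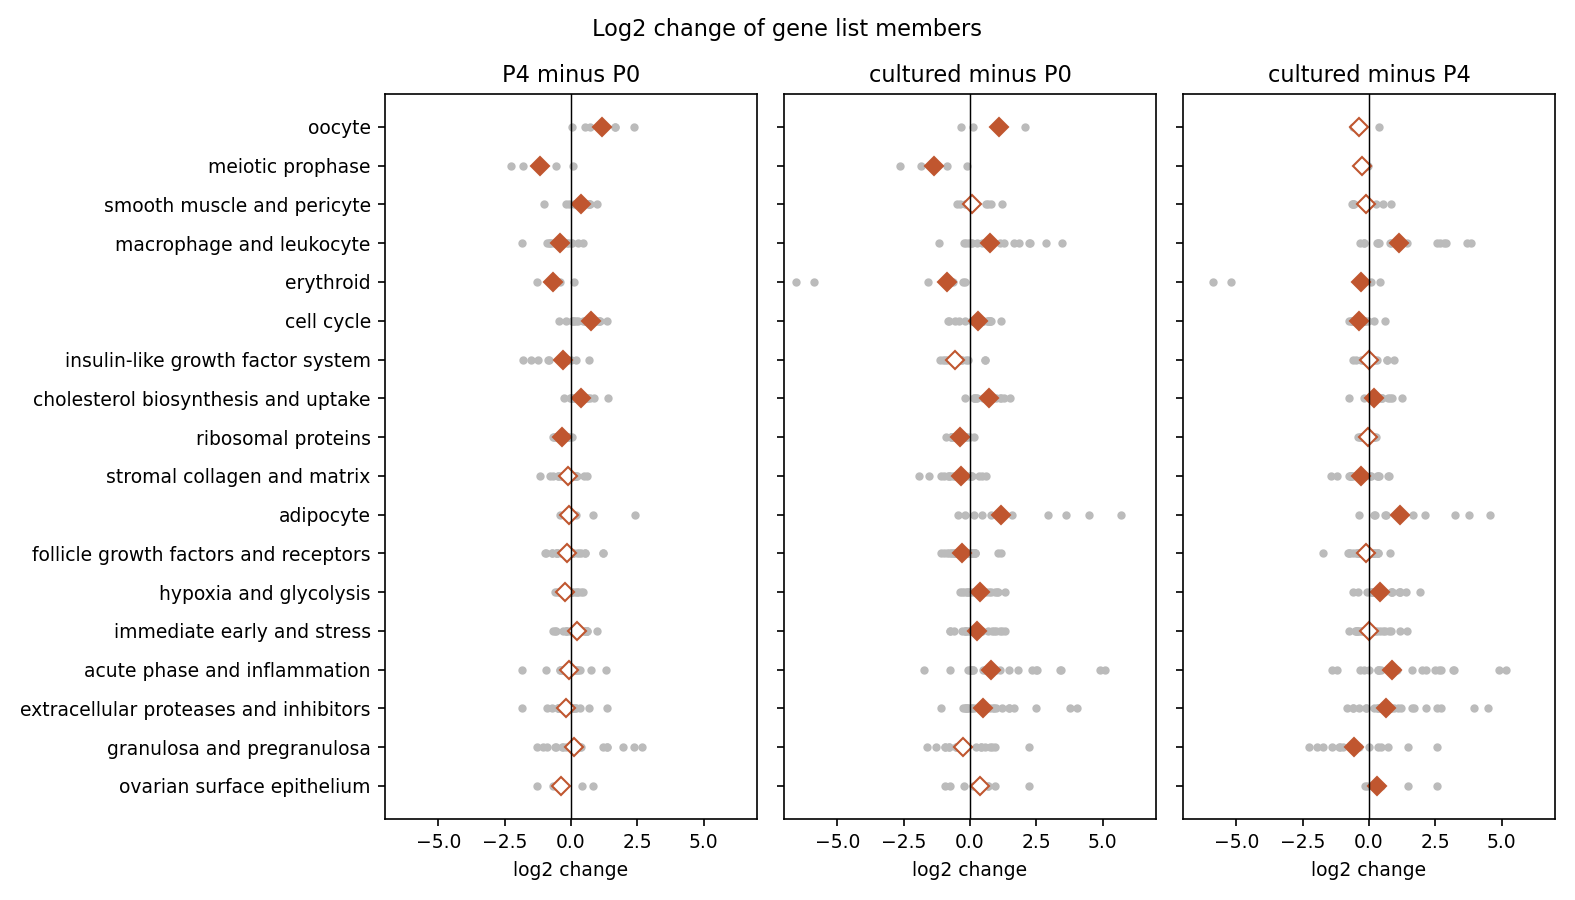
Log2 change of each measured member (grey points) and the list median (diamonds) for the gene lists that passed in at least 1 comparison, one panel per comparison; filled diamonds mark lists with a camera adjusted p under 0.05 and open diamonds the others. The median of the macrophage and leukocyte list was -0.42 for P4 against P0, 0.75 for cultured against P0 and 1.14 for cultured against P4.

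The other lists did not pass between cultured and P4 ovaries. Of 24 immediate early and stress genes 2 rose, none fell and 22 did not pass, also when adjusted over the list alone (camera adjusted p = 0.305). They were the heme oxygenase Hmox1 (log2 change 1.43, adjusted p = 0.0365) and the early response gene Ier3 (1.16, adjusted p = 0.048, or 0.32 on its other probe set). Amh was the 1 of 36 follicle growth factors and receptors that fell, with 35 not passing, also when adjusted over the list alone (camera adjusted p = 0.22). Of 53 oxidative phosphorylation genes Cox6c fell by 1.39 (adjusted p = 0.00935), against -0.07 on its other probe set, and 52 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0725). None passed among 40 genes of ribosomal proteins, also when adjusted over the list alone (camera adjusted p = 0.366, median -0.05, or 0.06 with quantile normalization). None of 10 endothelial genes (camera adjusted p = 0.82), 12 smooth muscle and pericyte genes (camera adjusted p = 0.452) or 13 insulin-like growth factor system genes (camera adjusted p = 0.861) passed, also when adjusted over the list alone. None of 9 skeletal muscle genes (camera adjusted p = 0.366) or 9 genes of kidney, adrenal, oviduct and liver (camera adjusted p = 0.539) passed, also when adjusted over the list alone. The adhesion molecule Vcam1 had a log2 change of 0.85 (adjusted p = 0.133) and the binding protein Igfbp3 one of 0.94 (adjusted p = 0.266). Of 12 nerve genes 2 rose and 10 did not pass, also when adjusted over the list alone (camera adjusted p = 0.539, median -0.01, mean 0.23, differing in sign). They were S100b (at least 7.61-fold, adjusted p = 0.00177) and Npy (adjusted p = 0.0058). None of 14 apoptosis genes passed, also when adjusted over the list alone (camera adjusted p = 0.71), with Bid at 0.89 (adjusted p = 0.176). None of 13 steroid receptors and chaperones passed, against 1 each way adjusted over the list alone (camera adjusted p = 0.335), with the orphan receptor Nr2f1 at 1.11 (adjusted p = 0.112). Npy lost the call without cultured replicate 1 (adjusted p = 0.0788). Hmox1 and Ier3 lost the call without P4 replicate 1 or either cultured array (highest adjusted p = 0.251 and 0.26), and Cox6c without P4 replicate 2 or cultured replicate 1 (highest adjusted p = 0.0872). Without P4 replicate 2 the immediate early and stress list passed upward (adjusted p = 0.0193) and the oxidative phosphorylation list downward (adjusted p = 0.0188), the latter also without cultured replicate 1 (adjusted p = 0.0244). The follicle growth factors and receptors list passed downward without P4 replicate 1 (adjusted p = 0.0398) and the smooth muscle and pericyte list without cultured replicate 1 (adjusted p = 0.00977).

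Changes from P0 to P4 were set beside changes from P0 to culture, to see which genes moved alike in the animal and in the dish. Among probe sets higher in both were Zp1, Zp2, Zp3, Star, Alox15, Pld1, Pllp, Dnmt1 and Abat, and among those lower in both were Sycp1, Sycp3, Cdh22, Egfl7 and Ces1dl1. In all, 32 were higher in both and 9 lower in both. The chemokine gene Cxcl13, singled out after its values were seen, was the 1 probe set called in opposite directions: it fell by 1.40 at P4 and rose by 1.25 in culture (adjusted p = 0.0376 and 0.0217). The fall lost its call without any 1 of the 6 arrays (highest adjusted p = 0.144) and the rise without P0 replicate 1, P0 replicate 2 or cultured replicate 1 (highest adjusted p = 0.126). Across probe sets, which are not independent replicates, Pearson's r was 0.488 and Spearman's rho 0.536. Both comparisons use the same P0 arrays, and unchanged groups simulated with independent arrays gave a Pearson r of 0.499 (0.474 to 0.523 in 100 simulations) and a Spearman rho of 0.475 (0.449 to 0.495). The covariance was 0.133, against a simulated 0.0412 (0.0383 to 0.0442). A simulation chosen after these results were seen let P0 and P4 arrays of the same chip ID batch correlate at 0.33, as they did in the data. It gave a Pearson r of 0.409 (0.376 to 0.434), a Spearman rho of 0.388 (0.357 to 0.421) and a covariance of 0.0276 (0.0253 to 0.0304). The Pearson r thus lay within the range simulated with independent arrays and above the range simulated with the batch correlation, while Spearman's rho and the covariance lay above both. The groups simulated with independent arrays gave 0.05 probe sets higher in both on average and 0.03 lower in both, at most 1 of each, but they also gave few calls in each comparison (0.29 and 0.2 higher on average). After these results were seen, the P0 arrays were split, 1 for each comparison, so that none was shared. With P0 replicate 1 set against P4 and P0 replicate 2 against culture, Pearson's r was 0.232 (simulated with independent arrays -0.0324 to 0.0502) and Spearman's rho 0.212 (simulated -0.0306 to 0.0486). In the reverse order they were 0.232 (simulated -0.0322 to 0.0288) and 0.205 (simulated -0.0275 to 0.0269). With the batch correlation, the simulated values of both splits were at most -0.0803 for r and -0.0827 for rho. These splits left 6 and 9 probe sets higher in both and 1 and 2 lower in both, with 0 and 2 called in opposite directions.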

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

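All alternatives named here were planned before the results were seen except the list tests with a block on the P0 and P4 arrays alone and the split of the P0 arrays. Between P4 and P0, 66 probe sets passed. The count was 23 with no filter, 29 with no trend in the variance prior, 23 with only the 4 arrays compared, and 127 at an adjusted p under 0.10. With the chip batch, which pairs P0 and P4 arrays by replicate number, as a replicate block, it was 314 on these 4 arrays, and it was 335 with the batch as a random block; all 66 were among the calls of each. Leaving out single arrays gave counts from 15 to 55. No named gene lost its call with this replicate block, and among lists it added only steroidogenesis.

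Between cultured and P0 ovaries 332 passed, against 569 at an adjusted p under 0.10 and between 90 and 353 with single arrays left out. Between cultured and P4 ovaries 170 passed, against 105 with the 60th percentile filter, 273 at an adjusted p under 0.10 and between 86 and 193 with single arrays left out. Where an array is left out, the remaining lone sample of its group is assumed to vary like the other groups. The replicate number as a replicate block over all 6 arrays gave 31 probe sets for P4 against P0, 255 for cultured against P0 and 141 for cultured against P4. Cultured arrays share only a number with the others (correlations of deviations -0.135 with P0 and -0.0537 with P4).

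Of 78 list tests 34 passed. None (0) passed with the correlation between genes estimated, where the smallest adjusted p was 0.357, and 8 passed with fry. The estimated variant rests on 3 residual degrees of freedom and could hardly pass. The oocyte list between P4 and P0 had an estimated correlation of -0.18, yet its camera adjusted p went from 5.02e-07 to 0.357. Whether correlation between genes accounts for the list shifts is therefore not settled. Of the 34, 3 no longer passed with quantile normalization, 3 with the chip batch as a random block, 2 with all named probe sets, 7 of 32 with the 60th percentile filter, and up to 5 with 1 array left out. None was lost with median centring, other pseudocounts, no filter, no variance trend or the replicate block. Of 115 called results of named genes, 26 were lost with no filter, 24 with no variance trend, 18 with the replicate block, 14 with quantile normalization, 12 with median centring, and up to 49 with 1 array left out (cultured replicate 1). None of them changed direction.

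Actb, which passed in no comparison, changed sign: for P4 against P0 its log2 change lay between -0.0825 (without P0 replicate 2) and 0.338 with single arrays left out, and was -8.575e-05 without P4 replicate 2, and for cultured against P0 it was 0.13 with quantile normalization. The Pearson r of the shared change lay between 0.426 and 0.593 with single arrays left out, and was 0.232 in either order with 1 P0 array for each comparison, which removes the shared arrays. Unless fewer arrays or probe sets were in the fit, the cause was not tested. Of the tested probe sets 98% exceeded the highest unspiked control intensity of 20 in at least 1 group, and dimmer ones limit fold values.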

Other observations

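The tests of explanations in this part were chosen after the results were seen. Values of single genes, counts of probe sets, list tests and calls lost without an array come from the comparisons and alternatives of the report. Several large changes belonged to genes outside the lists. Cuzd1, a membrane protein with zona pellucida-like domains, read 1260 ± 261 in cultured ovaries against 27.9 ± 8.91 at P0 (SD, n = 2; limma adjusted p = 5.57e-06), and it was also higher than at P4 (log2 change 5.36, adjusted p = 4.91e-06). The secreted phospholipase Pla2g2a read 1160 ± 1060 in culture against 46.5 at P0 (log2 change 4.06, adjusted p = 0.00364), with a wide spread between the cultured arrays. The angiotensin receptor Agtr2 was at least 6.37-fold lower in culture than at P0 (adjusted p = 0.00364), and Egfl7, a secreted protein of endothelial cells, at least 5.46-fold lower (adjusted p = 0.00123). Socs2, a brake on growth hormone signalling, was at least 3.5-fold lower than at P0 (adjusted p = 0.0133) and at least 3.93-fold lower than at P4 (adjusted p = 0.0108). It lost the first call without P0 replicate 2 or either cultured array (highest adjusted p = 0.102) and the second without P4 replicate 2 or either cultured array (highest adjusted p = 0.111). The matrix gene Tnc is in the stromal list through a probe set with a log2 change of -0.79 between cultured and P0 ovaries, which did not pass, but another of its probe sets was at least 3.2-fold lower (adjusted p = 0.00254). The fatty acid carrier Fabp3 fell from 369 ± 196 at P4 to 46.9 in culture (log2 change -2.69, limma adjusted p = 0.0022).

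More probe sets passed between P4 and P0 once the chip batch was a block. That the block fit leaves the cultured arrays out of the estimate of spread is not the reason in these values: without them and without a block 23 probe sets passed, against 66 with all arrays. Values shared within a chip batch are a candidate explanation: deviations of P0 and P4 arrays of the same batch correlated at 0.33, against at most -0.0537 for other pairs of groups. With 2 batches, a batch of hybridization and a shared litter or day of collection were not separated.

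The macrophage list shifted upward between P0 and cultured ovaries: 7 of 18 genes rose and 11 did not pass. The shift did not pass with an estimated correlation (adjusted p = 0.494), which could hardly pass here, or with fry (adjusted p = 0.156). A lower share of blood and of the main ovarian cells would raise the markers of all other cells alike, but the mean log2 changes of 6 lists ran from -0.25 (endothelial) over 0.07 (nerve), 0.19 (smooth muscle), 0.33 (surface epithelium) and 0.97 (macrophage) to 1.91 (adipocyte), a range of 2.16 (95% interval from 0.989 to 3.33 by the spread between arrays, widened for all 15 pairs of lists), which argues against it as the whole reason. Chip batches differed between the arrays of each group, so their differences are part of the replicate spread. The list mean rose by 0.97, with a 95% interval from 0.0696 to 1.87 by the spread of all 6 arrays and from -0.482 to 2.42 by that of the 4 compared. Batch differences stay open with so few arrays, and no cultured array shared a batch with a P0 array. Culture and age differed from P0 together, so a larger share of macrophages and a change within them may each contribute, and neither was tested.

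The granulosa list shifted downward between P4 and cultured ovaries: 3 of 20 genes fell, 2 rose and 15 did not pass, and the shift did not pass with an estimated correlation (adjusted p = 0.379). A lower share of granulosa cells would lower all of their markers alike, but the list median was -0.585 (bootstrap 95% interval from -1.03 to -0.186, 20 genes), the median of Inha, Amh and Cyp19a1 was -1.98, and Krt8 and Krt18 rose. Since both keratins are also markers of the surface epithelium, a lower share of granulosa cells and lower expression per cell cannot be told apart. The list mean fell by 0.447 (95% interval of the change from -0.846 to -0.0477 by the spread of all 6 arrays and from -0.824 to -0.0692 by that of the 4 compared). The list was taken up after its shift had been seen. P4 arrays lay in batches A and B and each cultured array in a batch of its own. A difference between those batches cannot be told apart from culture. Arrest of follicle growth in culture and the difference in age were not tested.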
